A study of Geobacter sulfurreducens with 6 samples.

How the data were processed

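RNA of Geobacter sulfurreducens strain PCA was sequenced from 6 cultures, 3 in NB and 3 in DB medium. Per the labels' protocols, cultures of 10 mL were kept at 35 °C, transferred 3 times and harvested in mid-exponential phase, and libraries were made with a stranded total RNA kit after depletion of ribosomal RNA. Samples were grouped by the medium and replicate number in their titles. Per the submitters' processing notes, HISAT2 2.2.0, featureCounts 2.0.1 and edgeR 1.14.5 were used; the strand setting of the counting and the genome build are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Reads shared between near-identical genes could likewise be split or dropped by the counting.

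The authors deposited raw counts for 3432 genes, per the file headers, and a workbook with normalized values for 3372 of them. The deposited normalized signal, named CPM in the file headers, was proportional to each raw count over the library's TMM effective size, with column sums between 969694 and 1026695. The deposited log2 fold changes (DB over NB) differed from the present fit by at most 3.7e-08. The deposited p-values differed by at most 1.3e-08 from those of edgeR's robust quasi-likelihood fit, which the present main test is not. Rows that name no gene numbered 0, and the counted genes included 0 of the 58 stable RNA genes in the reference gene table.

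Counts were tested in R 4.3.3 with edgeR 4.0.16, by its quasi-likelihood test (glmQLFit and glmQLFTest), TMM normalization and filterByExpr by medium, which left out 60 genes. The model held the medium alone, fold changes are DB over NB, and p-values were adjusted by Benjamini-Hochberg at 0.05. Standard errors were taken as the absolute log2 fold change over the square root of F, and 95% intervals used the total degrees of freedom of the fit. The common biological coefficient of variation was 0.170. Values given as normalized CPM are CPM computed on the TMM effective library size. Total counts of 21260219 to 24905001 per library and a median SE of 0.15 on the log2 scale set the precision.

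Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over the 25 of 31 lists with at least 5 measured members, and repeated with an estimated correlation and with fry. The lists were to be filled by locus tag, gene symbol and product; the tables used here give no product names, so locus tags and symbols alone were applied. Lists with fewer members were cytochrome c maturation and iron uptake (4 measured members each), mobile elements (2), and cyclic di-GMP, two-component regulators and stable RNA (0 each); they were not tested. Gene names came from the deposited table and, where that had none, from the RefSeq gene table of assembly ASM798v2, in which 3367 of the 3432 locus tags were found. Its coordinates were not used. Coding lengths from it, nearly all multiples of 3, served for checks on length and covered 98.6% of tested genes.

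The genes to name were, per direction, the 12 with adjusted p under 0.05 and the largest change among those without overlap between media. Where fewer passed, genes without overlap were filled in by the smallest unadjusted p. A fixed panel of 16 genes for cytochromes, pilins, exopolysaccharide and outer membrane proteins was added. Up to 4 members per list with the smallest p were added as well. The text prints only some of the list members that this rule chose, while the counts of values under alternatives cover all of them. The test, the lists, this rule and the alternatives listed next were fixed before the data were examined. Alternatives were RLE size factors, library totals alone, no filter on low counts, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited CPM with pseudocounts of 1 and 0.1, robust dispersions, an adjusted p under 0.01, and a log2 fold change of at least 1. Leaving out rRNA and tRNA genes was planned but could not be run, since the count table held none.

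The edgeR and camera steps were tested on simulated counts drawn from the real means, library sizes and dispersions for this comparison, with 200 genes changed in each of 5 simulations over 3366 to 3369 genes. Of the 100 genes changed 1.5-fold in each, 32.4% were recovered, and of the 100 changed 2-fold, 83.2%; 6.68% of calls were false. A further list of genes was shifted by a smaller fold to test camera, and its members were not counted as false calls. The simulated genes varied independently of each other, unlike real ones. No simulated library was made to stand apart, as NB replicate 1 and DB replicate 3 did in the real data. The recovered shares may therefore not hold for the real comparison.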

Results

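Transcripts of Geobacter sulfurreducens strain PCA, an anaerobic bacterium that can pass electrons to metals outside the cell, were counted in mid-exponential cultures grown in NB or DB medium. Both media held 15 mM acetate and 40 mM fumarate, and each medium had 3 biological replicates. The p-values therefore weigh the difference between the media against the spread among cultures of the same medium. The series title names ionic strength, the cell envelope, vesicles of the outer membrane and metal mineralization as its subject; the labels do not say how the media differ. Total counts per library were 21260219, 22055717 and 24905001 in NB replicates 1, 2 and 3, and 22722725, 23529886 and 23856795 in DB replicates 1, 2 and 3. The count table held 3432 genes, of which 3372 had enough counts to be tested. Each replicate pair differed by more than counting noise, with a chi-square per degree of freedom of at least 34.0. The first principal component, with 55.3% of the variance, set NB replicate 1 apart from the other libraries. The second, with 20.2%, set DB replicate 3 apart.

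**Figure D1:**
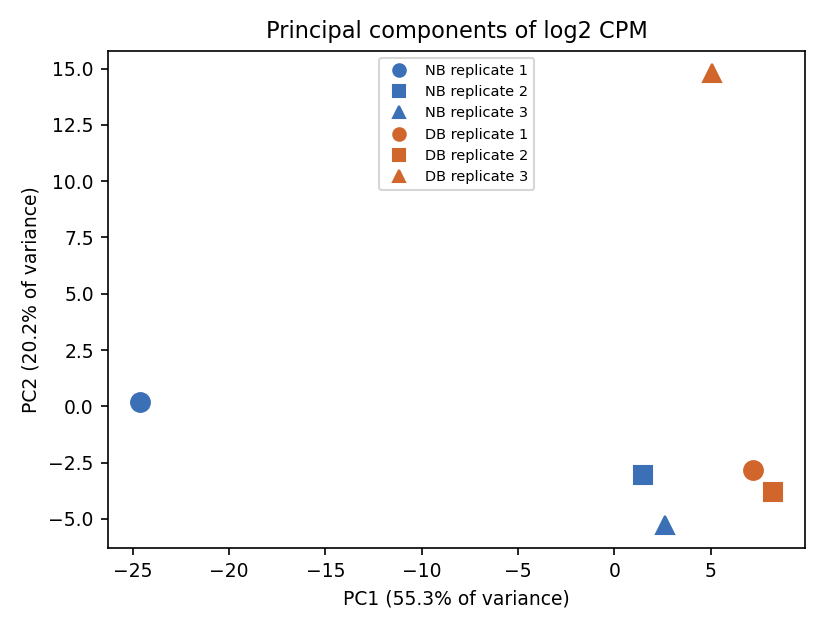
Principal components of log2 CPM over the tested genes, with 1 point per library, colour for the medium and shape for the replicate number. NB replicate 1 lies at -24.6 on the first component, while the other 5 libraries lie between 1.49 and 8.24, and DB replicate 3 lies at 14.8 on the second.

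The comparison of DB with NB asked which genes of this strain differ in level between the 2 media. The formate dehydrogenase genes fdnI (GSU0779), fdnH (GSU0778) and their neighbour fdhD/mobA-2 (GSU0780) had higher values in every DB library than in any NB library, and so did cooS (GSU2098), which encodes a carbon monoxide dehydrogenase. The level of fdnI was 1050 ± 99.3 normalized CPM in NB and 1692 ± 271 in DB (SD, n = 3 each), and that of cooS was 26.4 ± 6.49 in NB and 70.1 ± 22.6 in DB (SD, n = 3 each). Lower in every DB library were iscR-1 (GSU0534), whose product belongs to a family of iron-sulfur cluster regulators, at 2433 ± 224 in NB and 1759 ± 84.7 in DB, and the chaperone gene dnaJ (GSU0034), at 103 ± 5.86 in NB and 78.3 ± 2.07 in DB (SD, n = 3 each). None of these genes, and no other gene, passed edgeR's test over all genes. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.492. At an unadjusted p under 0.05 there were 303 genes, 138 higher and 165 lower in DB, where 169 would be expected if nothing changed. In the other divisions of the 6 libraries into 3 and 3 this count lay between 35 and 225, and 10 divisions are too few for a share under 0.05. DESeq2's Wald test called 17 genes, 8 higher and 9 lower in DB, among them cooS (adjusted p = 0.0032), fdnI (0.0203), iscR-1 (0.0364), fdnH (0.0414), dnaJ (0.0474) and fdhD/mobA-2 (0.0499). By contrast limma-voom and limma on the deposited normalized CPM called 0, with 304, 301 (pseudocount 1) and 299 (pseudocount 0.1) genes at an unadjusted p under 0.05.

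Among the 12 genes per direction with the smallest p and no overlap between the media, the log2 fold changes (DB over NB) were modest. For fdnI it was 0.69 (SE 0.14), for fdnH 0.76 (SE 0.17), for fdhD/mobA-2 0.88 (SE 0.22) and for fdnT (GSU0781) 0.53 (SE 0.13). It was 1.41 (SE 0.29) for cooS, 0.90 (SE 0.24) for bkdB (GSU2655), 1.13 (SE 0.29) for GSU3242 and 0.43 (SE 0.11) for ehrL (GSU0743). On the lower side were GSU1522 at -0.49 (SE 0.09), iscR-1 at -0.47 (SE 0.09), tusA-1 (GSU1352) at -0.48 (SE 0.10), GSU2353 at -0.66 (SE 0.13), GSU2354 at -0.54 (SE 0.12), GSU2357 at -0.42 (SE 0.09), GSU2360 at -0.52 (SE 0.12) and mleA (GSU2308) at -0.31 (SE 0.08). The other members of these 24 were GSU2485, omcA (GSU2884), GSU0182 and GSU1550 on the higher side, and GSU3506, GSU2140, dnaJ and GSU3497 on the lower side. All had an adjusted p of 0.492 by edgeR. DESeq2 called 15 of these 24. The media did not overlap for 888 genes, or 26.3% of those tested. The average over all divisions of the libraries into 3 and 3 is 10% by construction. Genes vary together, so a single division can lie far from that average. The share in the other divisions was not computed, so the 26.3% does not test for an effect of the medium. The 95% interval of the log2 fold change lay within 1 of 0 for 2991 genes.

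**Figure D2:**
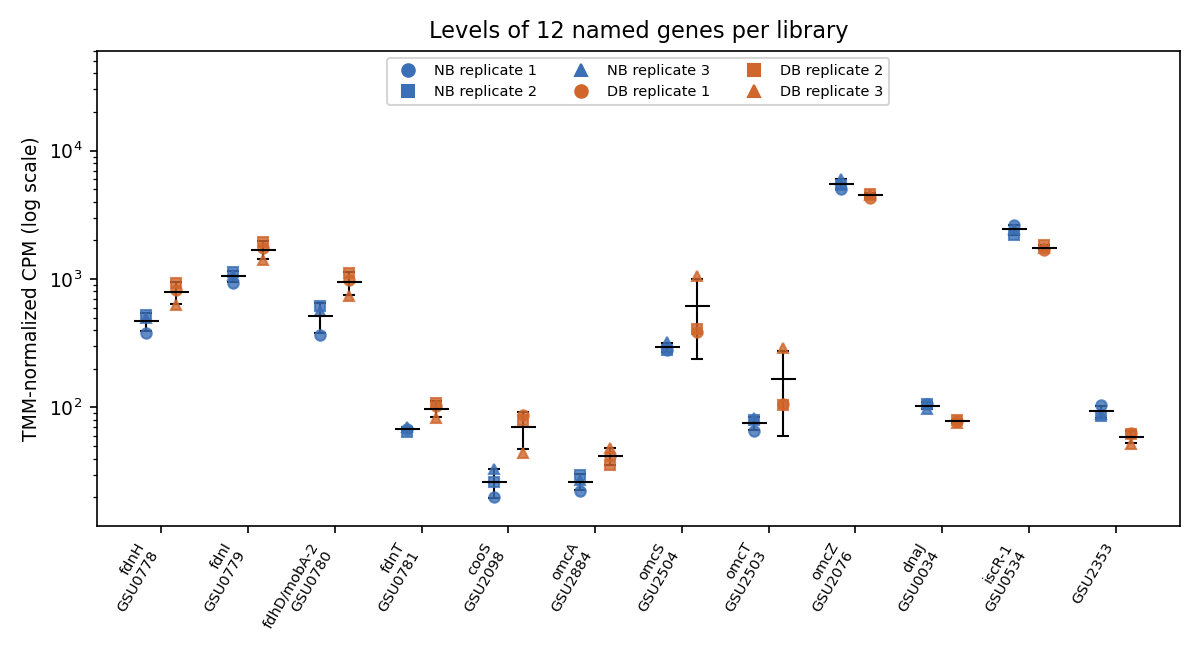
TMM-normalized CPM (log axis) of 12 named genes in each library, with points for libraries, horizontal marks for means and bars for the SD over 3 replicates. For omcS the value of 1052 in DB replicate 3 stands above the 390 and 409 of the other DB libraries, while the DB values of fdnI all lie above its NB values.

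Of 31 gene lists fixed before the data were examined, 25 had at least 5 measured members, and 4 passed camera with a preset correlation of 0.01 between genes. The ribosomal protein list fell in DB, with 53 of 56 members lower and a median log2 fold change of -0.27, or -0.13 without NB replicate 1. Its adjusted p by camera was 1.2e-13, but the call was lost with an estimated correlation (adjusted p = 0.924). Among its members, rpsB (GSU1921) had a log2 fold change of -0.29 (SE 0.09), rpsQ (GSU2848) of -0.40 (SE 0.13), or -0.24 without NB replicate 1, and rplK (GSU2867) of -0.28 (SE 0.10). The list of chaperones and proteases, which help proteins fold or degrade them, fell as well, with 16 of 19 members lower, a median of -0.27 and an adjusted p of 5.8e-05, which became an adjusted p of 0.783 with an estimated correlation. In it dnaJ stood at -0.40 (SE 0.10), dnaK (GSU0033) at -0.30 (SE 0.10), htpG (GSU2390) at -0.24 (SE 0.08) and clpP (GSU1792) at -0.34 (SE 0.12). The ATP synthase list fell too, with 10 of 10 members lower, a median of -0.19 and an adjusted p of 0.00114, lost with an estimated correlation (adjusted p = 0.924). In it atpF (GSU0109) stood at -0.28 (SE 0.09) and atpC (GSU0114) at -0.28 (SE 0.10), or -0.18 without NB replicate 1. The list of hydrogenases and formate enzymes rose in DB, with 29 of 35 members higher, a median of 0.23 and an adjusted p of 8.9e-06, also lost with an estimated correlation (adjusted p = 0.783). Over all genes, 0 members of these 4 lists passed the edgeR test, with 6 formate and hydrogenase genes higher at an unadjusted p under 0.05, and 19 ribosomal, 6 chaperone or protease and 3 ATP synthase genes lower. DESeq2 called fdnI, fdnH, fdhD/mobA-2 and dnaJ among them. Adjusted over the list alone, 4 members of the formate and hydrogenase list passed, namely fdnI, fdnH, fdnT and fdhD/mobA-2, and 0 members of the ribosomal, chaperone and ATP synthase lists did.

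No list passed with an estimated correlation. Other ways of dividing the 6 libraries into 3 and 3 gave up to 10 lists by the preset test, more than the 4 between the media. The mean level of each of these 4 lists did not overlap between the media. However, an exact permutation test on 3 against 3 libraries cannot go below p = 0.1, which each of them had (two-sided). The lists of envelope stability and oxidative stress, which did not pass camera, did not overlap either, so this does not set the 4 lists apart. With this exact permutation test adjusted over the 25 lists, all of them had an adjusted p of 0.417. NB replicate 1 was the library farthest from the others in 3 of the 4 lists that passed camera. For ribosomal proteins its mean log2 level was 0.33 above the mean of the 6 libraries, where the other NB libraries stood at 0.03 and -0.00459.

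**Figure D3:**
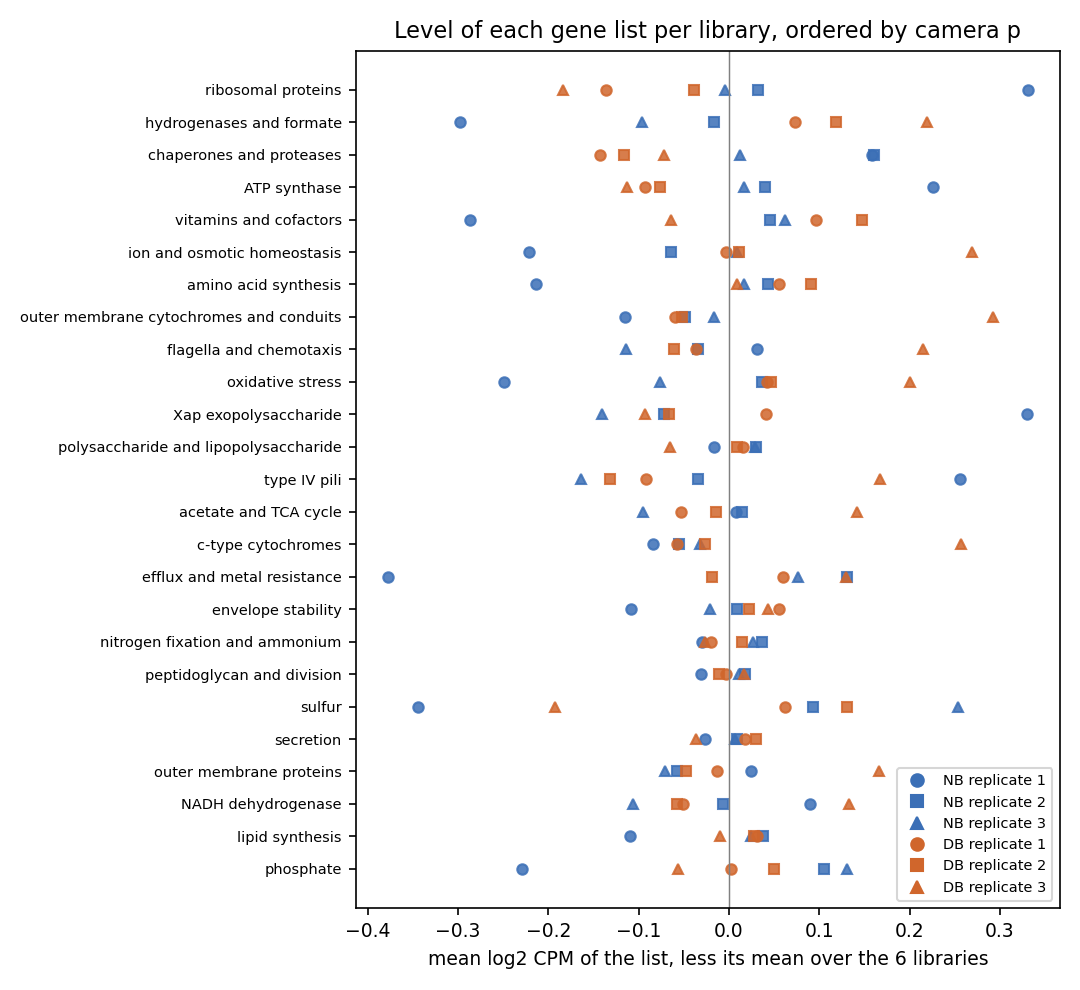
Mean log2 CPM of each of the 25 tested gene lists in each library, less the list's mean over the 6 libraries, ordered from the smallest camera p at the top. For ribosomal proteins NB replicate 1 lies at 0.33 and the DB libraries between -0.18 and -0.04.

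Genes for c-type cytochromes, heme proteins of which some carry electrons out of the cell, did not pass as lists or, by edgeR, as single genes. Both lists were filled by locus tag and symbol alone, so they do not stand for all cytochrome genes of the strain. The list of c-type cytochromes held fewer members than that of outer membrane cytochromes and conduits. In the list of c-type cytochromes 17 of 32 members had higher and 15 lower values in DB, and camera gave an adjusted p of 0.660; in the list of outer membrane cytochromes and conduits the numbers were 20 of 36 and 16, with an adjusted p of 0.588. By edgeR 0 members of either list passed over all genes and 0 adjusted over the list alone, with 5 higher and 2 lower at an unadjusted p under 0.05 in the first list and 7 higher and 1 lower in the second. The log2 fold change was 1.07 (SE 0.37) for omcS (GSU2504), whose product forms extracellular cytochrome filaments, and 1.15 (SE 0.39) for its neighbour omcT (GSU2503), both with an adjusted p of 0.492. DB replicate 3 decided these sizes, since without it they were 0.44 and 0.48. The genes omcG (GSU2882) and omcA stood at 0.58 (SE 0.17) and 0.67 (SE 0.17). DESeq2 called omcA (adjusted p = 0.0486). Another filament cytochrome gene, omcZ (GSU2076), stood at -0.30 (SE 0.09), with 5504 ± 473 normalized CPM in NB and 4479 ± 166 in DB (SD, n = 3 each). The conduit cytochrome gene omcB (GSU2737) stood at 0.06 (SE 0.11), omcC (GSU2731) at 0.28 (SE 0.30), omcE (GSU0618) at 0.29 (SE 0.19), GSU2645 of the ext clusters at 0.07 (SE 0.09), and the periplasmic and inner membrane genes ppcA (GSU0612), macA (GSU0466), GSU0274 and GSU3259 at -0.18 (SE 0.17), 0.06 (SE 0.18), -0.13 (SE 0.08) and -0.07 (SE 0.09). Single libraries decided several of these values. Without DB replicate 3 the value was 0.05 for omcE, -0.05 for omcB, -0.19 for omcC, -0.17 for macA and 0.12 for GSU2645. Without NB replicate 1 it was 0.18 for omcE, 0.00269 for omcB, 0.02 for GSU2645, 0.05 for ppcA, 0.15 for macA, -0.07 for GSU0274 and -0.00902 for GSU3259. Without NB replicate 2 it was 0.09 for omcB and -0.02 for macA. Without NB replicate 3 it was -0.32 for ppcA, 0.03 for macA and -0.12 for GSU3259. Without DB replicate 1 it was 0.12 for omcB, 0.05 for GSU2645 and 0.14 for macA. Without DB replicate 2 it was 0.51 for omcC, 0.05 for GSU2645, 0.17 for macA and -0.11 for GSU3259.

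Envelope genes did not pass as lists or, by edgeR, as single genes. For the type IV pilin gene pilA-N (GSU1496) the log2 fold change was 0.04 (SE 0.35), and for pilA-C (GSU1497), which lies beside it, 0.55 (SE 0.48). Without NB replicate 1 they stood at 0.51 and 0.96, and both turned negative without DB replicate 3, at -0.24 and -0.15. The value for pilA-N was also negative without NB replicate 2 (-0.10) or NB replicate 3 (-0.23), and 0.16 and 0.13 without DB replicates 1 and 2. That for pilA-C was 0.28 without NB replicate 3 and 0.84 without DB replicate 2. The porin gene ompJ (GSU3304), with 33286 ± 799 normalized CPM in NB and 34363 ± 243 in DB (SD, n = 3 each), had a log2 fold change of 0.05 (SE 0.07), or 0.03 without NB replicate 1, ompB (GSU1394) of 0.36 (SE 0.17), or 0.12 without DB replicate 3, and xapD (GSU1501) of -0.03 (SE 0.13), which turned positive without NB replicate 1 (0.07) or DB replicate 3 (0.03) and was -0.06, -0.12 and -0.11 without NB replicate 2, NB replicate 3 and DB replicate 1. By camera, the adjusted p was 0.630 for type IV pili, 0.588 for Xap exopolysaccharide, 0.618 for polysaccharide and lipopolysaccharide, 0.814 for outer membrane proteins and for lipid synthesis and secretion, and 0.808 for envelope stability and for peptidoglycan and division. For ion and osmotic homeostasis it was 0.161, with 14 of 19 members higher in DB, among them kdpE (GSU2484) at 0.43 (SE 0.20) and kdpB (GSU2481) at 0.37 (SE 0.18) of the potassium uptake system, which stood at 0.20 and 0.15 without DB replicate 3. Without DB replicate 1 this list passed the preset test (adjusted p = 0.0477), but not with an estimated correlation (adjusted p = 0.824). The closest other lists were vitamins and cofactors at 0.0962 and amino acid synthesis at 0.196. The vitamin list passed the preset test, higher in DB, without NB replicate 2 (adjusted p = 0.0199), NB replicate 3 (0.00773) or DB replicate 3 (2.7e-04), and the amino acid list without NB replicate 2 (0.0387) or DB replicate 3 (0.0325). With an estimated correlation these calls were lost, with an adjusted p for both lists of 0.989 without NB replicate 2 and 0.955 without DB replicate 3, and for the vitamin list of 0.958 without NB replicate 3. In the lists of this paragraph 0 members passed edgeR's test over all genes and 0 adjusted over the list alone. The remaining lists, flagella and chemotaxis, oxidative stress, acetate and TCA cycle, efflux and metal resistance, nitrogen, sulfur, NADH dehydrogenase and phosphate, had adjusted p between 0.588 and 0.99. Sulfur passed the preset test, lower in DB, without NB replicate 1 (adjusted p = 0.0116), and lost the call with an estimated correlation (adjusted p = 0.865). Among them 1 gene passed adjusted over the list alone, the formate dehydrogenase gene fdnI, which entered the nitrogen list through a reference symbol.

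Taking an unadjusted p under 0.05 together with an absolute log2 fold change of at least 0.58, limits that the submitters' sheets carry in their names, gave 67 genes, 40 higher and 27 lower in DB. The authors' deposited table lists 40 genes as higher and 27 as lower under these limits, and the present fit placed 40 and 27 of them past both limits. In the authors' deposited table the smallest adjusted p is 0.49961 and 297 genes have p under 0.05. The number of genes past both limits was 41 without NB replicate 1, 116 without NB replicate 2 and 137 without NB replicate 3. The balance turned to 17 higher and 24 lower without NB replicate 1 and to 27 higher and 43 lower without DB replicate 3. Of the 67 genes, 48 fell under the fold limit when some single library was left out, 29 of them without NB replicate 1 and 24 without DB replicate 3, omcS and omcT included in the latter. In 4 of the 67, the level in 1 library was over 3 times that in every other, with at least 100 reads in it. These were GSU1080 (log2 fold change 4.46, high in DB replicate 1), GSU2122 (-4.19, high in NB replicate 1), GSU0705 (-1.70) and GSU1652 (-1.53), the last 2 high in NB replicate 3. Without the library in question they stood at -0.60, -0.50, -0.27 and -0.25 in the same order. They were singled out after their values were seen.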

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

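The tests of a coding length trend and a wrong label for NB replicate 1, of NB replicate 1 alone behind the ribosomal change, and both tests on genes high in a single library were chosen after the result was seen. The test of NB replicate 1 alone was redefined after earlier outcomes were seen: passing the preset test without it had first been read against it, and the estimated correlation used next could not decide, since the list did not pass with it in all 6 libraries either. The gene GSU2158 lies outside the tested genes and had 41929 reads in DB replicate 2, or 0.178% of that library, against at most 8 reads in any other library. It drew attention as a signal that the main test left out. The alternative with no filter on low counts kept all 3432 genes.

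GSU2158 was the largest of 14 genes whose level in 1 library was over 3 times that in every other library, with at least 100 reads in it. Of the 14, 13 were tested. To test a change along an operon, the genes on either side were taken by locus tag number alone, without strand or known operons. The 26 with a mean count of at least 20 had a median log2 ratio of -0.0219 in the same library, and 0 were raised 2-fold. This argues against a change shared with these neighbours, but whether they share an operon with the gene was not known. Reads moved from another gene are argued against by a test whose outcome depends on its definition: against the median of the other libraries 7.14% of the cases, 1 of 14, had a gene with a matching loss, but against their mean, the definition used first, 78.6% had one. The median was adopted after that value was seen, because genes among the 14 raise the mean; with those genes not counted as losing, the mean also gave 1 of 14. A transcript of a single gene in 1 culture and copies of a cloned or amplified gene in 1 library both stay open, and no biological explanation was tested, since the design gives none for a single library.

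NB replicate 1 stood apart from the other 5 libraries. Its mean correlation of log2 CPM with NB replicates 2 and 3 was 0.0145 below the correlation between those 2 libraries. Lower sequencing depth is argued against by the close totals, 21260219 in NB replicate 1 and 22055717 to 24905001 in the others. Thinning all libraries to the smallest total left 99.5% of this gap. With totals this close, thinning could hardly have changed the gap, so it adds little. A trend on coding length is argued against as the whole cause, with 93.6% of the gap left after removing it. A wrong medium label is argued against, since its lowest correlation with an NB library exceeded its highest with a DB library by 0.00463. A difference in the state of that culture stays open and was not tested.

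Ribosomal protein genes were lower in DB by the preset test, also without NB replicate 1 (adjusted p = 4.8e-10) and without both distant libraries (3.3e-05), but that test gave at least 4 lists in 8 of the 10 splits, and with an estimated correlation the adjusted p was 0.924, 0.865 and 0.864 in the same order. NB replicate 1 alone stays open as the cause: without it the median moved from -0.27 to -0.13, still below 0, while the mean level in DB less that in NB was -0.13, within the range of 0.14 among the DB libraries. A trend on coding length may account for part of the pattern: random lists matched on coding length and level had a mean median of -0.18, which is 66.6% of the list's median. The match used level as well as length, so length by itself was not separated, and 0% of the 10000 matched lists had a median as low. A difference between the media stays open as an untested biological explanation.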

How the results depend on the processing

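The count of 0 genes with adjusted p under 0.05 was found again with RLE factors, library totals, no filter and robust dispersions. It was also found with limma-voom, with limma on deposited CPM and without any single library. The stricter limits could give no other count, so they are no check. Without a single library, 166 (without DB replicate 1) to 369 (without NB replicate 1) genes had an unadjusted p under 0.05, against 303. Without DB replicate 3 there were 201. DESeq2 called 17, and the cause was not tested. Leaving out NB replicate 1 and DB replicate 3 together, an alternative chosen after seeing the data, gave 35 genes, 13 higher and 22 lower in DB, with 724 at an unadjusted p under 0.05; these libraries were picked for their distance from the rest, so this is not an independent count. The labels do not say whether a replicate number marks a shared inoculum or day. The correlations of same-numbered deviations from the group means were -0.04, 0.10 and -0.19. Those of other pairs reached -0.20 (NB replicate 1 with DB replicate 2) and 0.21 (NB replicate 3 with DB replicate 2). These few values cannot decide whether the samples are paired. With the replicate block, 0 genes passed, 83 genes passed both unadjusted limits against 67, and 4 lists passed.

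The 67 genes past both unadjusted limits ranged from 41 to 137 when 1 library was left out, and became 62 without both distant libraries and 63 without the genes high in a single library, both chosen after seeing the data. Of the lists, 4 passed under each scaling, and 4 to 6 without 1 library, but 0 with an estimated correlation and 0 with fry. With an estimated correlation the adjusted p was 0.924 for ribosomal proteins and for ATP synthase and 0.783 for the chaperone and the hydrogenase and formate lists. With fry, which does not compare a list with other genes, it was 0.523 for ribosomal proteins, 0.364 for ATP synthase and for hydrogenases and formate, and 0.213 for chaperones. The estimated correlations lay on 4 residual degrees of freedom. Without a single library, also chosen after seeing the data, 0 lists passed with an estimated correlation: the adjusted p of these 4 lists was 0.355 without NB replicate 1 (ribosomal proteins 0.865), 0.989 and 0.958 without NB replicates 2 and 3 (chaperones 0.444 in the latter), and 0.824, 0.859 and 0.955 without DB replicates 1, 2 and 3; without both distant libraries it was 0.694 (ribosomal proteins 0.864). Of 2100 values under alternatives, for 40 genes of the top lists and the panel, 96 further list members and 4 genes high in a single library, 2085 kept their side of the threshold and 15 passed it, all by DESeq2 and each a different gene. The sign differed in 27, of which 25 without a single library, over 19 genes.

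The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes and the highest other 0, with all 10 splits as large. With a real count of 0 this could not come out otherwise, and the comparison was chosen after the result was seen. The real split gave 67 genes past both limits against 74 in the highest other, with 2 splits as large. It gave 4 lists against 10, with 8 splits as large. Both splits with 10 lists put NB replicate 1 and DB replicate 3 in the same group, so the preset test also calls lists on the structure among the libraries.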

Other observations

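The test in the next paragraph was chosen after the result was seen. In the list for acetate and the TCA cycle 16 of 30 members had higher and 14 lower values in DB, and camera gave an adjusted p of 0.652. By edgeR 0 members passed over all genes and 0 adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0. Its 4 members with the smallest p were aplD (GSU0518), with a log2 fold change of 0.34 (SE 0.12), sucA, korD and dcuB. The 2-oxoglutarate dehydrogenase gene sucA (GSU2449) had a log2 fold change of 0.45 (SE 0.16) and the korD gene (GSU1467), for a subunit of the ferredoxin-dependent enzyme acting on the same substrate, of -0.29 (SE 0.13), both with an adjusted p of 0.492. The dcuB gene (GSU2751), for a dicarboxylate transporter, stood at 18557 ± 1588 normalized CPM in NB and 25527 ± 7968 in DB (SD, n = 3 each), a log2 fold change of 0.46 that was 0.17 without DB replicate 3. Without NB replicate 1 sucA stood at 0.29 and korD at -0.17.

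The strain has 2 clusters of NADH dehydrogenase genes. All 14 genes from GSU0338 to GSU0351 had lower values in DB (median log2 fold change -0.24), and all 17 from GSU3429 to GSU3445 had higher values (median 0.19), while 0 genes of either passed the edgeR test. As a hypothesis, the medium may shift the balance of the clusters. The mean log2 level of the second cluster less that of the first was -3.39 ± 0.38 in NB and -2.99 ± 0.08 in DB (SD, n = 3 each), without overlap, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows, so the hypothesis stays open. NB replicate 1, at -3.83, lay farthest from the other libraries, so part of the difference came from it. NB replicates 2 and 3 stood at -3.22 and -3.13, nearer to DB replicates 1, 2 and 3, at -3.03, -3.05 and -2.90.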
